A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

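Per the labels' protocols, splenocytes were pooled and pDCs were sorted directly into a phenol-based lysis reagent, whereas the cultured lines were washed, pelleted and lysed. Equal amounts of total RNA of each sample went through 2 rounds of linear amplification, with biotin added in the second round. The deposited values are linear intensities, 1 per probe set, and the 2% trimmed mean of each array was 250.0, so the authors had scaled every array to a common mean. The software that summarised the probes is not given in the sources used here. The mouse arrays carried 45101 probe sets and the human arrays 54675.

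Groups were taken from the sample titles and source names, with 2 arrays in each of 4 groups and no other columns in the tables (0 unused). Gene names came from the platform annotation. Of the mouse probe sets, 34958 had 1 gene symbol, 932 several and 9211 none, and 34754 of the 34958 were matched by gene identifier to a RefSeq table of assembly GRCm38.p6, used for names alone. Of the human probe sets, 41097 had 1 symbol, 1801 several and 11777 none. No gene was named from a probe set with several symbols, and human symbols are those of the annotation and can be old. No coordinates are given because no genome build is named in the files. Mouse and human genes were matched by symbol regardless of case.

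The deposited scaling was kept, and log2(intensity + 16) was tested, a scale that understates the change of dim genes. Each gene was represented by the probe set with the highest mean over the 4 arrays of its comparison. Control probe sets and genes below the 40th percentile of mean level were left out. The percentile fell at an intensity of 31.7 in the mouse and 86.1 in the human arrays and left 10916 of 18193 and 11865 of 19775 genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2 residual degrees of freedom), adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot give a p under 0.333. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

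Before the data were examined, 20 gene lists were fixed from general knowledge of these cells, and 19 held at least 3 tested genes in the mouse and 18 in the human comparison. Lists were matched by symbol or older symbol, which brought Lyz1 and Cd1d2 into mouse lists. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. With an estimated correlation no list passed in either comparison. Even the human T cell list, with 17 of 24 genes lower in CAL-1, had a camera adjusted p of 0.175 there. The correlation is then estimated with 2 residual degrees of freedom, and this setting was not simulated. It may have little power, so not passing under it does not argue against a list. Named genes followed a rule fixed in advance: Tcf4; up to 4 called members of each list with the lowest p; the 10 highest and 10 lowest fold changes among called genes whose arrays did not overlap; and the 5 genes per direction with the lowest mouse p among the human-derived sets. It takes 91 mouse and 73 human genes, all past the threshold, of which the text names a part, picked after their values were known; other list members in the text were also picked then, and a sex-linked human gene is left out. For the third comparison, the 200 called genes with the highest and the 200 with the lowest fold change between the human lines were tested in the mouse comparison with camera.

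In the human arrays, the 95th percentile of 27 Bacillus subtilis control probe sets over all 4 arrays, an intensity of 168, served as a floor for folds. It was chosen after seeing the data, as was cyclic loess normalization. In the mouse arrays these control probe sets read up to 14896, so they gave no floor there. The 2 arrays of a group correlated with r = 0.981 (wild type), 0.993 (heterozygous), 0.861 (CAL-1) and 0.825 (MOLT-4) across genes, and between groups r was 0.937 to 0.948 in the mouse and 0.625 to 0.638 in the human arrays.

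The tests were run on simulated data drawn from the real means and variances with 200 changed genes and a changed list of 25 more, 10 times per comparison. Far fewer genes changed there than were called in the data, which makes the adjusted threshold stricter, so the recovered shares may be too low. Over 10916 mouse genes, 84.8% of 2-fold and 99.4% of 4-fold changes were recovered, and 7.37% of the calls were unchanged genes. Over 11865 human genes the shares were 10.5%, 39.3% and 6.40%. A moved list of 25 genes was called (camera p under 0.05, not adjusted) in 10 of 10 simulations of each comparison and an unmoved list in 0. Genes were drawn independently and all members of the moved list changed alike. The simulation therefore cannot show how often camera calls a list of correlated genes wrongly.

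Alternatives were quantile normalization, cyclic loess, pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, no intensity trend, the mean of all probe sets, probe sets not ending in _s_at or _x_at, every probe set, a threshold of 0.10, a 2-fold minimum, the replicate number as a block, the human floor, sets of 100 and 500 genes, limma's fry, an estimated correlation and leaving out each array. With an array left out, its lone partner is assumed to vary like the other group. The mean of the probe sets of a gene includes dim ones that fell under the filter when tested on their own.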

Results

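Transcript levels were measured on 8 single-colour Affymetrix arrays in 4 groups of 2. The mouse arrays compared plasmacytoid dendritic cells (pDCs, the immune cells specialised in type I interferon secretion) of mice carrying 1 intact and 1 disrupted copy of E2-2 with those of wild-type littermates. E2-2 is an E protein transcription factor, and its gene is listed as Tcf4. The cells had been flow-sorted from spleen as CD11b-negative, CD11c-low, B220-positive and Bst2-positive. The human arrays compared CAL-1, an established pDC line, with MOLT-4, an established T cell leukaemia line. Genes tested numbered 10916 in the mouse and 11865 in the human comparison. The number of arrays limits the precision, and the labels do not say whether the 2 arrays of a group came from separate pools or cultures, so the p-values measure the spread between these arrays, which may be technical.

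The first comparison addressed how the transcript levels of pDCs differ when 1 copy of E2-2 is disrupted. The targeted gene, Tcf4, was 1.88-fold lower in heterozygous than in wild-type cells (log2 fold change -0.91 ± 0.11 SE, n = 2 per group, limma adjusted p = 0.000912). The chemokine receptor Ccr9, which directs cells to the small intestine, was 5.23-fold lower, and Dntt, the template-independent DNA polymerase of lymphoid progenitors, was 11.6-fold lower. The integrin Itgax (CD11c), the transcription factor Irf4 and the chemokine receptor Ccr6 were 4.02-fold, 3.62-fold and 4.36-fold higher. Fosb and Egr1, immediate early genes that respond to stimulation, were 3.45-fold and 3.43-fold higher, and the interferon-stimulated gene Isg20 was 3.97-fold lower.

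All 5 tested probe sets of Tcf4 were lower in heterozygous cells, and the intensities of the brightest were 8190 and 7548 on the wild-type arrays against 4041 and 4317 on the heterozygous arrays. The log2 fold change of Tcf4 was smaller after cyclic loess (-0.59), after quantile normalization (-0.62) and on the mean of all its probe sets (-0.53). That mean includes a further probe set too dim to be tested on its own. Its intensities were 6.54 to 29.1 and its log2 fold change 0.49. Where these probe sets lie relative to the disrupted part of the gene is not given in the sources used here, so they may not check the genotype labels. Over all genes tested, 2260 were higher and 2168 lower in heterozygous cells at an adjusted p under 0.05, of which 634 and 549 changed at least 2-fold. These calls made up 40.6% of the genes tested, so a list of arbitrary genes would also hold calls in both directions. Leaving out heterozygous replicate 1 left 2305 genes past the threshold, leaving out replicate 2 left 2312, and the mean of all probe sets of a gene gave 2839. Among the called genes with more than 1 tested probe set, 426 of 2489 had a probe set called in the opposite direction.

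The arrays of the 2 genotypes also differed in their controls. The beta-actin 3′/5′ ratio, a marker of RNA integrity and of the length of the amplified RNA, was 34.5 and 25.4 on the wild-type arrays and 8.10 and 8.40 on the heterozygous arrays. The Gapdh 3′/5′ ratio was 27.9 and 24.6 against 7.69 and 8.34. Genes of high intensity moved one way: of the 268 genes with a mean log2 level of at least 13, 0 were higher and 223 lower in heterozygous cells (limma), with a median log2 fold change of -0.81. Of the 2001 genes between 8 and 9, 575 were higher and 271 lower, with a median of 0.15.

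**Figure D1:**
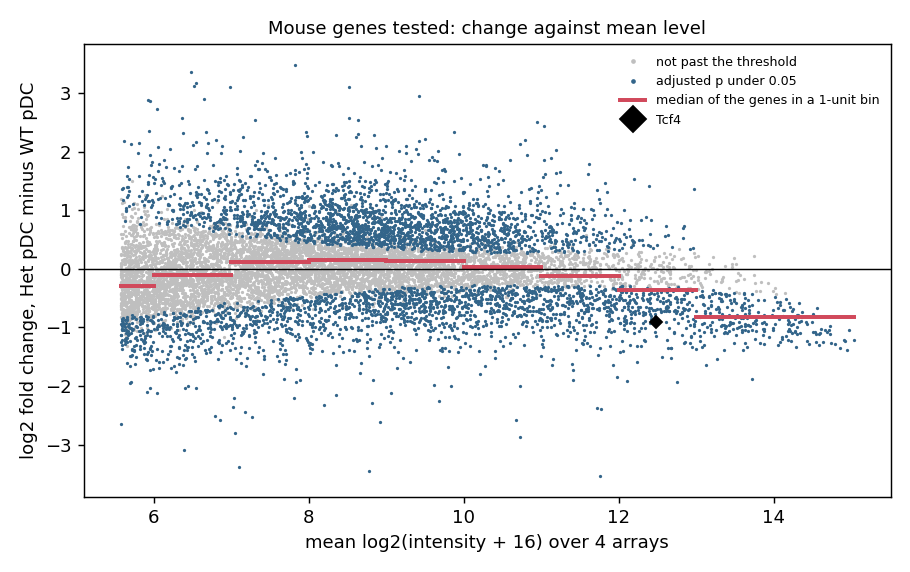
Log2 fold change (heterozygous minus wild type) of each mouse gene tested against its mean log2(intensity + 16) over the 4 arrays, with blue points past the threshold, red lines at the median of each 1-unit bin of level and Tcf4 as a black diamond. The median is 0.15 between levels 8 and 9 and falls to -0.81 at levels of at least 13, where no gene is called higher.

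Of the 36 tested genes of the mouse pDC list, 6 rose, 16 fell and 14 did not pass, and adjusted over the list alone 8 rose and 17 fell. As fixed, the list also named Bst2 and Ptprc, which encodes B220, and the sort had gated on both proteins. Ccr9 (log2 fold change -2.39 ± 0.10 SE), Dntt (-3.54 ± 0.16), the CD4 co-receptor gene Cd4 (-1.90 ± 0.18) and Fcrla, an intracellular Fc receptor-like protein (-1.32 ± 0.11), fell, and Cd8a, a co-receptor also carried by some pDCs, rose by 2.44 ± 0.09. On the mean of all probe sets the values were -1.43 for Ccr9, -2.55 for Dntt and -0.96 for Cd4. Fcrla did not pass when probe sets ending in _s_at or _x_at were left out (-0.06). The list as a whole did not pass camera (adjusted p = 0.0553 in limma's camera test, 0.853 with an estimated correlation). Its balance depended on the scaling: 14 members rose and 12 fell after quantile normalization, and 14 rose and 14 fell after cyclic loess. The list passed downward without wild-type replicate 2 (adjusted p = 0.0429), heterozygous replicate 1 (0.0435) or heterozygous replicate 2 (0.0336), with fry (0.0354), on the mean of probe sets (0.0128) and without probe sets ending in _s_at or _x_at (0.0384).

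Of the 11 pDC transcription factors, 1 rose, 4 fell and 6 did not pass (adjusted over the list alone, 2 rose and 4 fell; camera adjusted p = 0.355). Next to Tcf4, the fallers were Tsc22d1 (log2 fold change -1.28 ± 0.23 SE), the corepressor gene Cbfa2t3 (-0.95 ± 0.12) and Irf8, a factor needed for dendritic cell development (-0.91 ± 0.18). Tsc22d1 lay at -0.60 after cyclic loess and -0.30 after quantile normalization. Irf8 lay at -0.25 after cyclic loess, and at 0.01 with an adjusted p of 0.835 after quantile normalization, and leaving out heterozygous replicate 1 or 2 gave it adjusted p-values of 0.115 and 0.0779. Tsc22d1 and Cbfa2t3 each had 1 probe set called upward, and neither passed on the mean of all probe sets (adjusted p = 0.142 for Tsc22d1 and 0.314 for Cbfa2t3). Of the 6 E proteins and Id proteins, Tcf3 rose by 0.61 ± 0.13 and Tcf4 fell (adjusted over the list alone, 1 rose and 2 fell; camera adjusted p = 0.786), but the call of Tcf3 ended without heterozygous replicate 1 (adjusted p = 0.0512) or 2 (0.142), and on the mean of its probe sets (0.0662). Of the 15 genes of nucleic acid sensing and interferon induction, 1 rose and 4 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.602). The riser was Slc15a4, a lysosomal transporter needed for endosomal sensing (0.92 ± 0.10, and 0.52 on the mean of its probe sets), and the fallers included Irak1, a kinase of the Toll-like receptor pathway (-1.15 ± 0.13, and -0.47 on the mean of its probe sets), which had 3 probe sets called lower and 1 called higher.

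**Figure D2:**
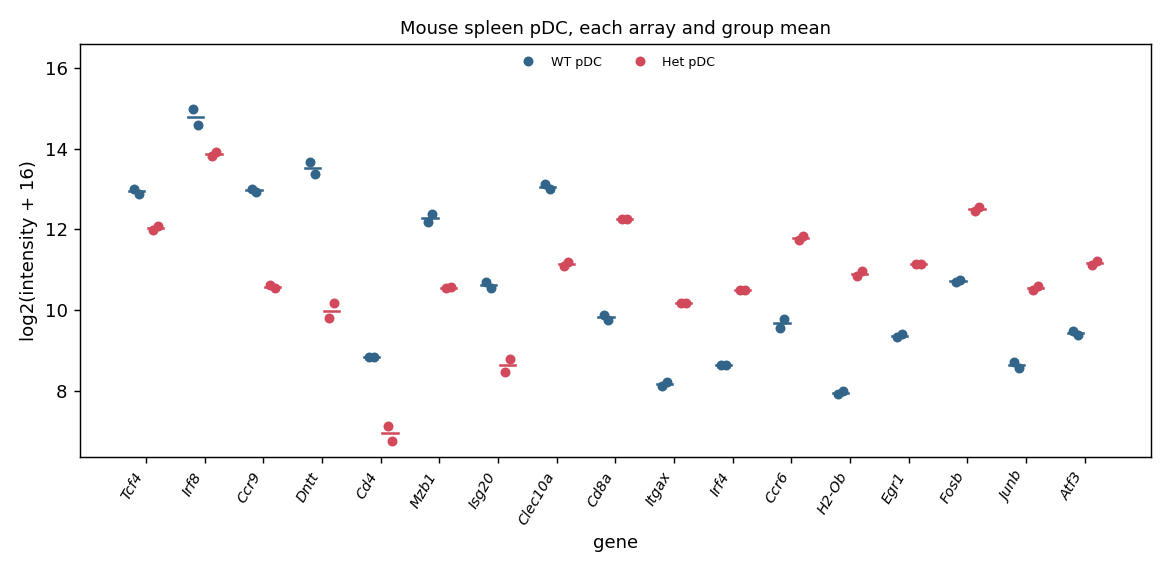
Log2(intensity + 16) of 17 named genes on each mouse array, with wild-type pDCs in blue, heterozygous pDCs in red and a short line at the mean of the 2 arrays of a group. Both wild-type arrays lie above both heterozygous arrays for Tcf4, Ccr9 and Dntt, and below them for Cd8a, Itgax, Irf4 and Ccr6; the separation of Irf8 is not present after quantile normalization.

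Interferon-stimulated genes were lower in heterozygous cells. Of 20 tested, 12 fell, 1 rose and 7 did not pass (14 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -0.53 and a camera adjusted p of 0.000808 (adjusted p = 0.479 with an estimated correlation). Isg20, an exonuclease acting on RNA, fell by 1.99 ± 0.13 SE on the log2 scale. Rsad2, which encodes viperin, fell by 1.03 ± 0.13, the 2′-5′ oligoadenylate synthetase gene Oas1a by 0.79 ± 0.13, and Usp18, which removes ISG15 from proteins, by 0.77 ± 0.13. Rsad2 did not pass on the mean of its probe sets (adjusted p = 0.188). The list kept its call after cyclic loess (13 fell and 1 rose, camera adjusted p = 0.00103) and after quantile normalization (0.00242). The beta-actin 3′/5′ ratio, 34.5 and 25.4 against 8.10 and 8.40, separated the same arrays, and its part in these changes was not tested. The chemokine gene Cxcl10 went against the list and rose.

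The immediate early and heat shock genes showed the lowest camera p of the lists fixed for the mouse. Of 20 tested, 16 rose, 3 fell and 1 did not pass, with the same counts adjusted over the list alone, a median log2 fold change of 1.10 and a camera adjusted p of 1.44e-06 (adjusted p = 0.479 with an estimated correlation). The AP-1 subunit genes Fosb and Junb rose by 1.79 ± 0.10 SE and 1.91 ± 0.11, and the stress-induced transcription factors Egr1 and Atf3 by 1.78 ± 0.09 and 1.75 ± 0.10. Hspa8, a constitutive chaperone, Jund and Dnajb1 fell. After cyclic loess, 17 rose and 2 fell.

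Conventional dendritic cell genes were higher in heterozygous cells. Of 22 tested, 11 rose, 3 fell and 8 did not pass (12 and 4 adjusted over the list alone), with a median log2 fold change of 0.48 and a camera adjusted p of 0.00648 (adjusted p = 0.479 with an estimated correlation). Itgax rose by 2.01 ± 0.11 SE, Irf4 by 1.86 ± 0.10 and Dpp4, a surface peptidase, by 1.56 ± 0.11, whereas the lectin gene Clec10a (-1.91 ± 0.10), Ccl22 and Cd86 fell. Irf4 lay at 0.94 and Dpp4 at 0.68 on the mean of all probe sets. As fixed, the list named Itgax and Itgam, which encode CD11c and CD11b, and the sort had gated on both proteins. Among the 10 MHC class II genes, 4 rose and 5 fell (5 and 5 adjusted over the list alone), with a median of -0.21, a mean of 0.11 and an upward camera direction (adjusted p = 0.788). H2-Ob, a subunit of the H2-O modulator of peptide loading, rose by 2.95 ± 0.11, H2-DMb2 by 1.54 ± 0.12 and H2-Oa by 0.84 ± 0.12. Cd74, H2-Aa, H2-Ab1 and H2-Eb1, the invariant chain and the classical class II chains, fell. The class II protease gene Ctss fell by 1.05 ± 0.17, a call lost without heterozygous replicate 1 (adjusted p = 0.0632), and lay at -0.42 after cyclic loess and -0.22 after quantile normalization. After quantile normalization 4 class II genes rose and 1 fell, and the list passed upward (adjusted p = 0.0199).

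Markers of other cells of the spleen moved in both directions, as did all genes tested, of which 40.6% passed the threshold. Mixed counts are therefore not particular to these markers. Of 22 monocyte, macrophage and neutrophil genes, 10 rose and 6 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.602). Risers included Cd14, a co-receptor for lipopolysaccharide (log2 fold change 1.46 ± 0.11 SE), the calprotectin subunit gene S100a9 (1.52 ± 0.13) and Lyz2, lysozyme (1.01 ± 0.10). Of 17 B cell genes, 5 rose and 4 fell, as they did adjusted over the list alone (camera adjusted p = 0.654). Ms4a1, which encodes CD20, rose by 1.03 ± 0.10 (0.47 on the mean of its probe sets), and Vpreb1, part of the surrogate light chain of B cell precursors, fell (-1.23 ± 0.23, and -0.75 with a pseudocount of 64). Of 17 T cell genes, 7 rose and 2 fell in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.0952). The CD8 beta chain gene Cd8b1 rose by 1.55 ± 0.09 and Cd5, a negative regulator of antigen receptor signals, by 1.37 ± 0.17, whereas Cd4, also on the pDC list, fell by more than either rose (-1.90 ± 0.18). The T cell list passed upward after cyclic loess (adjusted p = 0.0320), after quantile normalization (0.0344), with fry (0.0422) and on the mean of probe sets (0.0128).

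Of 11 natural killer and cytotoxic genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.682, fry 0.0354), with the cystatin F gene Cst7 up by 2.89 ± 0.26 SE and the granzyme gene Gzma by 2.33 ± 0.24 on the log2 scale. Ctsw, a cathepsin of cytotoxic cells, fell by 0.67 ± 0.13, a call lost without heterozygous replicate 2 (adjusted p = 0.0668). Of 9 erythroid genes, 6 fell and 1 rose in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.0175, and adjusted p = 0.479 with an estimated correlation). Slc4a1, the band 3 anion exchanger of red cells, fell by 2.38 ± 0.11 and Alas2, the erythroid enzyme that starts haem synthesis, by 1.08 ± 0.12. The alpha globin gene Hba-a2 rose by 2.87 ± 0.25, while the beta globin gene Hbb-b2 fell (-2.15 ± 0.14). How far Hba-a2 and Cst7 rose depends on the pseudocount, as given below, so their values are not exact. Slc4a1 lay at -1.44 on the mean of its probe sets. Of 17 chemokine receptor and homing genes, 7 rose and 4 fell in both counts, over all genes and adjusted over the list alone (camera adjusted p = 0.703). Ccr6 rose by 2.13 ± 0.11 and Gpr183, an oxysterol receptor that positions cells in lymphoid tissue, by 1.68 ± 0.10, while Ccr9, also on the pDC list, fell (-2.39 ± 0.10). Of 13 genes of T cell leukaemia and the Notch pathway, 3 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.993; median 0.32, mean -0.007), among them the receptor genes Notch3 (-1.15 ± 0.12) and Notch1 (-0.75 ± 0.11). Of 3 sex-linked genes, Eif2s3y rose by 0.49 ± 0.13, also adjusted over the list alone (camera adjusted p = 0.682), and lost its call without heterozygous replicate 1 (adjusted p = 0.120) or 2 (0.0604).

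Cell cycle genes were lower: of 25 tested, 2 rose and 8 fell, with the same counts adjusted over the list alone, a median log2 fold change of -0.47 and a camera adjusted p of 0.0202 (adjusted p = 0.479 with an estimated correlation). The proliferation marker Mki67 (-0.99 ± 0.15 SE) and Cdca8, a subunit of the chromosomal passenger complex (-1.33 ± 0.11), fell, whereas the replication factor genes Pcna and Mcm2 rose. Without probe sets ending in _s_at or _x_at the list did not pass (adjusted p = 0.332), nor did Cdca8 (0.368). Of 28 endoplasmic reticulum and secretory pathway genes, 6 rose and 8 fell (7 and 8 adjusted over the list alone; camera adjusted p = 0.602), with Mzb1, a chaperone cofactor of antibody secretion (-1.72 ± 0.10), and the translocon subunit gene Sec61b (-1.38 ± 0.15) among the fallers; Sec61b lay at -0.91 after cyclic loess and -0.84 after quantile normalization. With limma's fry this list (adjusted p = 0.0354) and the apoptosis list (0.0105) passed downward. Of 11 apoptosis regulators, 2 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.602). The pro-apoptotic gene Bid rose by 0.97 ± 0.17 and its anti-apoptotic relative Bcl2l1 fell by 0.72 ± 0.13, but they did not pass on the mean of all probe sets (adjusted p = 0.112 for Bid and 0.258 for Bcl2l1).

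Among genes whose arrays did not overlap between genotypes, the highest fold changes in heterozygous cells included those of the chitinase-like gene Chil3 (11.2-fold), the fatty acid receptor Ffar4 (10.3-fold), the inhibitory receptor Ctla4 (9.04-fold), the proton-sensing receptor Gpr4 (8.66-fold), Stox2 (8.61-fold) and the receptor activity modifier Ramp3 (8.55-fold). The lowest included Dntt, the urate transporter Slc22a12 (log2 fold change -3.45), Tm4sf5 (10.4-fold lower), Crispld2 (8.51-fold lower), Jakmip1 (7.28-fold) and the lactate dehydrogenase subunit gene Ldhb (5.98-fold, in 4 of 4 tested probe sets). The order depends on the pseudocount: with 1 in place of 16, log2 fold changes were 4.42 for Ffar4, 4.38 for Cst7, 4.27 for Hba-a2 and 4.08 for Ctla4, above 3.82 for Chil3. With 64 they were 2.14 for Ffar4, 2.05 for Ctla4, 2.01 for Gpr4, 1.603 for Cst7 and -1.93 for Crispld2. On the mean of all probe sets Stox2 lay at 0.82, Slc22a12 at -1.73, Jakmip1 at -1.16 and Ldhb at -1.63. Crispld2 did not pass on the mean of all probe sets (adjusted p = 0.131), and Slc22a12 and Jakmip1 did not pass without probe sets ending in _s_at or _x_at (adjusted p = 0.989 for Slc22a12 and 0.0738 for Jakmip1).

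The second comparison asked which genes set a pDC line apart from a T cell line. Each cell type was represented by CAL-1 or MOLT-4 alone. A difference between the cell types therefore cannot be told apart from a difference between these lines. CAL-1 cells held 17.9-fold more TCF4 transcript than MOLT-4 cells (log2 fold change 4.16 ± 0.17 SE, n = 2 per group, limma adjusted p = 2.83e-06), and all 8 TCF4 probe sets were called higher. IRF8 was 104-fold higher, and TCL1A, a coactivator of the AKT kinase carried by pDCs and B cells, was at least 128-fold higher. CD74, the class II invariant chain, was at least 42.7-fold higher and LYZ, lysozyme, at least 150-fold higher. MOLT-4 held at least 88.0-fold more CD3D, a subunit of the T cell receptor complex, and 29.4-fold more of the T cell transcription factor LEF1. A fold written "at least" has a dimmer group below the 95th percentile of the bacterial control probe sets (an intensity of 168), which then takes its place.

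In all, 1201 genes were higher and 961 lower in CAL-1 at an adjusted p under 0.05, of which 1039 and 811 changed at least 2-fold. These calls made up 18.2% of the genes tested. The GAPDH 3′/5′ ratio was 2.54 and 2.60 on the CAL-1 arrays and 10.2 and 7.80 on the MOLT-4 arrays, and the 18S ribosomal RNA control read 88794 and 79714 against 5350 and 5189. The beta-actin 3′/5′ ratio did not follow that of GAPDH, with 43.6 and 48.4 on the CAL-1 and 28.9 and 46.1 on the MOLT-4 arrays. The count fell to 284 when limma's prior variance did not follow intensity, to 953 on the mean of all probe sets, to 1338 without probe sets ending in _s_at or _x_at, and to 1255 and 1321 without CAL-1 replicate 1 and 2. The balance of directions followed the array left out: without CAL-1 replicate 1 or 2, 529 and 597 genes were higher and 726 and 724 lower in CAL-1, and without MOLT-4 replicate 1 or 2, 1128 and 1114 were higher and 534 and 460 lower. In simulated data for this comparison 10.5% of 2-fold and 39.3% of 4-fold changes were recovered over 11865 genes, so genes that did not pass may still differ. The simulation changed far fewer genes than were called here, which makes the adjusted threshold stricter, so these shares may be too low.

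The human pDC list was higher in CAL-1: of 43 genes tested, 22 rose, 1 fell and 20 did not pass (22 and 2 adjusted over the list alone), with a median log2 fold change of 1.96 and a camera adjusted p of 1.50e-10 (adjusted p = 0.175 with an estimated correlation). Next to TCL1A, CCDC50, a regulator of receptor signalling, was at least 65.8-fold higher and TCL1B at least 40.4-fold higher. The mean of the probe sets of CCDC50 gave a log2 fold change of 4.20. Among pDC transcription factors, 6 of 11 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.0172, and adjusted p = 0.269 with an estimated correlation). IRF8 (log2 fold change 6.70 ± 0.39 SE), RUNX2 (3.64 ± 0.32) and CBFA2T3 (2.51 ± 0.23) rose, and IRF8 lay at 6.01 without MOLT-4 replicate 1 and at 7.39 without replicate 2. The fallers, named after their values were seen, were ETV6, TSC22D1, BCL11A and IKZF1. RUNX2 did not pass on the mean of all probe sets (adjusted p = 0.295), and the list did not pass with the filter at the 60th percentile (0.0524). Of 6 E proteins and Id proteins, TCF4 and ID2, an antagonist of E proteins (at least 14.1-fold higher), rose, and TCF12 (-1.63 ± 0.18) and TCF3 (-1.51 ± 0.18) fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.969). The median of these 6 genes was -0.69 and the mean 0.78, and camera gave a downward direction. TCF3 lay at 0.26 without probe sets ending in _s_at or _x_at, and TCF12 did not pass on the mean of its probe sets (adjusted p = 0.243).

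Genes of nucleic acid sensing rose in 6 of 16 cases and fell in 0, with 10 not passing (6 and 1 adjusted over the list alone; camera adjusted p = 0.0214, and adjusted p = 0.269 with an estimated correlation). SLC15A4 rose by 3.36 ± 0.17 SE on the log2 scale, and the interferon regulatory factor genes IRF7 and IRF5 were at least 6.40-fold and 5.99-fold higher. Without CAL-1 replicate 1 the list had an adjusted p of 0.0528 and IRF7 one of 0.0862, and the list did not pass without the intensity trend (0.0677) or without probe sets ending in _s_at or _x_at (0.213). IRF5 did not pass on the mean of its probe sets (adjusted p = 0.0684). Interferon-stimulated genes went the other way: of 15 tested, 1 rose, 4 fell and 10 did not pass, as adjusted over the list alone (camera adjusted p = 0.0173, and adjusted p = 0.328 with an estimated correlation). CMPK2, a mitochondrial nucleotide kinase, was at least 13.6-fold lower and MX2, a dynamin-like antiviral GTPase, at least 5.05-fold lower. Without CAL-1 replicate 1 or MOLT-4 replicate 2 the list did not pass (adjusted p = 0.111 and 0.109), nor with limma's fry (0.104) or the filter at the 60th percentile (0.145).

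Of 11 MHC class II genes, 8 rose, 0 fell and 3 did not pass, as adjusted over the list alone, with a median log2 fold change of 3.67 and a camera adjusted p of 1.38e-06 (adjusted p = 0.194 with an estimated correlation). CD74 was at least 42.7-fold higher, HLA-DPA1 at least 35.0-fold and HLA-DMA, which helps load peptides, at least 9.94-fold. On the mean of all probe sets CD74 had a log2 fold change of 2.80 and HLA-DPA1 one of 4.02. Of 19 conventional dendritic cell genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.000551, and adjusted p = 0.269 with an estimated correlation), with the lipid-presenting molecule CD1C up by 2.65 ± 0.21 SE on the log2 scale and CSF2RB, the common beta chain of cytokine receptors, by 2.71 ± 0.46 (3.35 without MOLT-4 replicate 1 and 2.07 without replicate 2). Of 6 monocyte, macrophage and neutrophil genes, LYZ, LST1 and CEBPB rose, also adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.269 with an estimated correlation). LYZ had a log2 fold change of 4.98 on the mean of its probe sets and did not pass without probe sets ending in _s_at or _x_at (1.26), nor did LST1 (adjusted p = 0.168) and CEBPB (0.113) without CAL-1 replicate 1. The list itself did not pass without the filter (adjusted p = 0.110), with the floor of the bacterial controls (0.0790) or without probe sets ending in _s_at or _x_at (0.145).

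**Figure D3:**
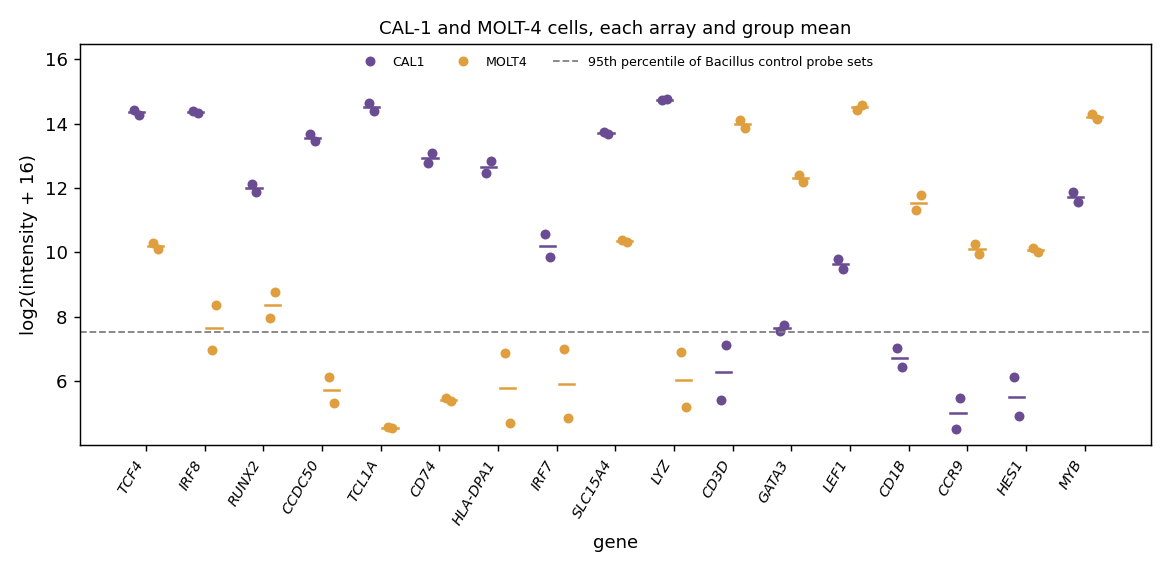
Log2(intensity + 16) of 17 named genes on each human array, with CAL-1 in purple, MOLT-4 in orange, a short line at the mean of the 2 arrays of a group and a dashed line at the 95th percentile of the bacterial control probe sets. Both CAL-1 arrays lie above both MOLT-4 arrays for TCF4, IRF8, CD74 and LYZ, and below them for CD3D, GATA3 and LEF1.

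T cell genes were lower in CAL-1. Of 24 tested, 17 fell, 0 rose and 7 did not pass (18 and 0 adjusted over the list alone), with a median log2 fold change of -4.24 and a camera adjusted p of 1.73e-12 (adjusted p = 0.175 with an estimated correlation). The fallers included CD3D, LEF1, which acts in the Wnt pathway (-4.88 ± 0.19 SE, and -2.94 on the mean of its probe sets), the thymocyte antigen gene CD1B (at least 16.3-fold lower) and GATA3, a regulator of T cell development (-4.65 ± 0.28). Of 14 genes of T cell leukaemia and the Notch pathway, 3 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.159), including the Notch target HES1 (at least 5.82-fold lower) and the proto-oncogene MYB (-2.49 ± 0.17, and -1.87 on the mean of its probe sets). Of 13 chemokine receptor and homing genes, 4 rose and 4 fell, as adjusted over the list alone (camera adjusted p = 0.580). The integrin chain gene ITGB7 was at least 7.37-fold higher, and CXCR4, the CXCL12 receptor, fell (-1.99 ± 0.19). CCR9 was at least 6.02-fold lower, a call lost without MOLT-4 replicate 1 (adjusted p = 0.0580).

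Of 28 endoplasmic reticulum and secretory pathway genes, 8 rose, 0 fell and 20 did not pass (10 and 0 adjusted over the list alone; camera adjusted p = 0.000877, and adjusted p = 0.269 with an estimated correlation). HERPUD1, a factor of protein degradation at the endoplasmic reticulum, rose by 1.71 ± 0.20 SE and the translocon-associated gene SSR4 by 1.58 ± 0.24. The list did not pass with fry (adjusted p = 0.0661), nor HERPUD1 without probe sets ending in _s_at or _x_at (0.205). Of 29 cell cycle genes, 4 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.752), with a median log2 fold change of 0.02 and a downward camera direction. Cyclin A2 (CCNA2) fell by 1.08 ± 0.15. Of 10 apoptosis regulators, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.580), with the pro-apoptotic gene BIK up by 2.71 ± 0.34. Of 13 immediate early and heat shock genes, JUND rose by 2.65 ± 0.25 and EGR1 fell by 2.06 ± 0.43, also adjusted over the list alone (camera adjusted p = 0.573). JUND did not pass on the mean of all probe sets (adjusted p = 0.448), and EGR1 did not pass without MOLT-4 replicate 1 (0.0711).

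Of 11 B cell genes, 3 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.446), with IGLL1, a surrogate light chain component, at least 6.38-fold higher. Of 6 erythroid genes, the carbonic anhydrase gene CA2 and the transcription factor gene GATA1 rose, at least 3.89-fold and 3.02-fold, also adjusted over the list alone (camera adjusted p = 0.406). Of 3 natural killer and cytotoxic genes, CST7 rose at least 4.03-fold (2 and 1 adjusted over the list alone; camera adjusted p = 0.463). Without CAL-1 replicate 1 these calls ended for CA2 (adjusted p = 0.172), GATA1 (0.246) and CST7 (0.230), and without replicate 2 likewise (0.126, 0.0702 and 0.148). GATA1 did not pass on the mean of its probe sets (adjusted p = 0.515).

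Among genes whose arrays did not overlap between the lines, the highest computed fold changes in CAL-1, which had a dimmer group below the floor and so no measured order, included TCL1A, MT1E, a metallothionein that binds zinc and copper (at least 118-fold), the calcium-binding gene S100A4 (at least 117-fold), PDLIM1 (at least 80.3-fold), the macrophage perforin-like gene MPEG1 (at least 57.0-fold) and TGFBI (at least 50.0-fold). The lowest included DNTT (at least 112-fold lower), ITM2A (at least 88.1-fold), the cadherin FAT1 (at least 39.5-fold), the transcription factor ETS1 (at least 37.8-fold) and the retinaldehyde dehydrogenase ALDH1A2 (at least 35.7-fold). ETS1 had a log2 fold change of -2.91 and ALDH1A2 one of -4.08 on the mean of all probe sets. When the prior variance did not follow intensity, 39 of the 73 genes that the naming rule takes in this comparison did not pass.

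The third comparison asked whether genes that separate the human lines move with the E2-2 genotype in mouse cells. Of the 200 genes highest in CAL-1, 138 were tested in the mouse by the same symbol: 21 rose and 42 fell in heterozygous cells, and the set did not pass camera (adjusted p = 0.417). Of the 200 highest in MOLT-4, 100 were tested, 25 rose and 18 fell, and the set did not pass (adjusted p = 0.631). The median and mean of the MOLT-4 set, 0.07 and -0.003, differed in sign. Of the 5 genes per direction with the lowest mouse p, 6 were in the CAL-1 set: S100a4 (log2 fold change 2.10 ± 0.12 SE), the Fc receptor gamma chain gene Fcer1g (1.62 ± 0.10), the immunoglobulin joining chain gene Jchain (2.51 ± 0.17) and Cst7 rose, and the membrane-binding annexin gene Anxa2 (-1.90 ± 0.10, and -0.79 on the mean of its probe sets) and Fcrla fell. The other 4 were in the MOLT-4 set: Dntt, Ccr9 and Bex1 (-2.36 ± 0.19, and -1.70 with a pseudocount of 64) fell, and the protein kinase C gene Prkch rose (1.76 ± 0.15, and 1.18 on the mean of its probe sets). Across the 7733 genes matched by symbol, which are not independent replicates, the fold changes had a Spearman rho of -0.037.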

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

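The tests of 3-prime bias, handling, cell share and conventional dendritic cell content were chosen only after the results they bear on had been seen, and so were the level-matched tests of the lists, whose values after cyclic loess were already known; the level-matched test of Tcf4 was set before its value was computed. Several signals outside the tested genes differed between groups. The beta-actin 3′/5′ ratio averaged 3.63 times higher on the wild-type than on the heterozygous arrays, and that of Gapdh 3.28 times higher. The hybridization spike-in probe sets averaged 3.50 times higher on the wild-type arrays. Poly-A spike-ins, which are Bacillus transcripts, had a median 3-prime intensity of 4068 and 4745 on the wild-type arrays. On the heterozygous arrays it was 1018 and 1003. These transcripts do not come from the mouse cells, and why they differed was not tested. In the human arrays, the GAPDH 3′/5′ ratio averaged 3.50 times higher in MOLT-4 than in CAL-1, and the 18S ribosomal RNA control 16 times higher in CAL-1. Their beta-actin ratio did not go the way of GAPDH (28.9 and 46.1 in MOLT-4, 43.6 and 48.4 in CAL-1). Of the probe sets without a gene name here, 848 of 4124 in the mouse (410 higher and 438 lower in heterozygous cells) and 257 of 6004 in the human comparison (136 higher and 121 lower in CAL-1) passed the threshold.

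The first pattern is that bright genes, with Tcf4 and much of the pDC list among them, were lower in heterozygous cells. For the pDC list, the excess of falling members may come from a shift shared by all genes of that level: after the median of the 200 genes nearest in level was taken off each member, the median of the list was -0.003, at the 48.7th percentile of 10000 lists matched on level. Tcf4 lay 0.54 log2 units below the median of its 200 neighbours, at their 11.5th percentile, between the values set beforehand for and against this explanation, so its drop cannot be told apart from the shift by this test, although it stayed past the threshold after cyclic loess (log2 fold change -0.59, adjusted p = 0.00150). A difference in 3-prime bias, with actin ratios 3.63-fold apart, cannot be told apart from the genotype because probe positions were not used. The disrupted copy of E2-2 stays open as a biological explanation and was not tested apart from these.

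The second pattern is the rise of immediate early and heat shock genes in heterozygous cells. A shift shared by genes of the same level would leave the list near 0 after correction, but its corrected median was 1.09, at the 100th percentile of the 10000 matched lists, which argues against that explanation. A difference in handling before or during the sort could raise these genes and stays open: members of the list differed by a median of at most 0.126 log2 units between the 2 arrays of a genotype, so handling shared by a genotype cannot be told apart from the genotype. An effect of E2-2 dosage was not tested apart from these.

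The third pattern is the rise of the conventional dendritic cell list (camera adjusted p = 0.00648, and adjusted p = 0.479 with an estimated correlation), whose level-corrected median of 0.53 lay at the 99.99th percentile of 10000 lists matched on level; the T cell and monocyte lists lay at the 100th and 99.81th percentiles but did not pass camera (adjusted p = 0.0952 and 0.602), and the MHC class II list lay at the 88.0th. For a lower share of pDCs in the heterozygous sort, the prediction was that all other cell types rise alike. Medians of 6 lists of other cell types, without genes on more than 1 of them or on the pDC list, spanned 1.53 log2 units. This range was wider than shuffled list labels give (97 genes, permutation p = 0.00560 from 10000 shuffles that treat genes as independent), against the prediction. It rests on the erythroid list, with 9 genes and a median of -1.02, as the other 5 medians lay between 0.09 and 0.51. A lower share of pDCs stays open, because the log2 change of a list also depends on its level in the pDCs and need not be alike. More conventional dendritic cells could contribute, although the sort was gated on CD11b-negative, CD11c-low, B220-positive and Bst2-positive cells, which selects against them. The prediction was that genes which conventional dendritic cells use and pDCs lack all rise. Of the list, 11 members rose, but Clec10a (-1.91 ± 0.10 SE), Ccl22 and Cd86 fell. The members that rose, a group chosen by the outcome, had a mean wild-type log2 level of 9.04. None is known to be absent from pDCs, so the test could not decide. Of the 22 conventional dendritic cell genes tested, 2 are in another of the lists. An effect of E2-2 dosage on the pDCs themselves was not tested apart from these.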

How the results depend on the processing

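Cyclic loess and the human floor were chosen after seeing the data, and the cause of the changes below was not tested. Where an array was left out, fewer arrays entered. The mouse count of 4428 genes stayed within 1.5 times in 12 alternatives and moved to 1183 with a 2-fold minimum, 7797 with every probe set tested on its own and 2839 on the mean of probe sets. Leaving out 1 array gave 2305 to 6326. The human count of 2162 stayed within 1.5 times in 13 alternatives and moved to 284 without the intensity trend, 953 on the mean of probe sets and 1338 without probe sets ending in _s_at or _x_at. Leaving out 1 array gave 1255 to 1662. The sets from the human lines passed under none of 23 alternatives each. Their adjusted p-values with an array left out ran from 0.169 to 0.848 for the CAL-1 set and from 0.509 to 0.941 for the MOLT-4 set, and a change of sign between values that do not pass is not counted as a reversal.

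With the replicate number as a block, 4907 mouse and 2816 human genes passed, and the set p-values were 0.855 and 0.982. Deviations of arrays with the same number correlated at -0.020 in the mouse and 0.019 in the human arrays. These values gave no sign of pairing by number, but with 1 difference per group they cannot exclude it. The block brought the mouse pDC list past the threshold (camera adjusted p = 0.00999) and ended no call of a list or named gene.

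Of the list results, 282 of the human alternatives kept their side of the threshold and 21 lost it, and of the mouse ones 281 kept it, 6 lost it and 15 gained it. Of the named-gene results, 1201 mouse and 947 human ones kept the call, 48 and 112 lost it, and these changed sign. Irf8 had a log2 fold change of 0.0136 after quantile normalization. On the mean of probe sets, Mcl1 lay at 0.0389. Without probe sets ending in _s_at or _x_at, Mcl1 lay at 0.91, Atf4 at 1.002, Hyou1 at 0.25, Rrm2 at 0.26, HLA-DPB1 at -1.97 and TCF3 at 0.26. A gene that falls under the filter in an alternative has no value there. In the human arrays, 43 of the 73 genes of the naming rule had a dimmer group below the floor of the bacterial controls, which limits their folds to bounds.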

Other observations

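The gene families, the overlap and the AXL-related list were chosen only after the comparisons had been seen. In the human arrays, most families defined by symbol differed between the lines with camera's preset correlation. None did with an estimated one, a setting that may have little power here. Pseudogenes, antisense RNAs and other genes that share a symbol without being members were taken out after values with them had been seen. All 6 tested metallothionein genes, which buffer zinc and copper, were higher in CAL-1, with a median log2 fold change of 4.67 (camera adjusted p = 1.07e-09, and 0.163 with an estimated correlation), among them MT1E and MT2A, which was 23.9-fold higher. All 4 tested GIMAP genes, GTPases of lymphocyte survival, were lower in CAL-1, with a median of -2.86 (adjusted p = 0.000222, and 0.168 with an estimated correlation), and GIMAP7 was at least 9.57-fold lower. Of 66 respiratory chain genes, 32 were higher and 3 lower in CAL-1 (adjusted p = 2.24e-11, and 0.163 with an estimated correlation), and of 34 proteasome genes 17 were higher and 0 lower (2.01e-06, and 0.168). Cytosolic ribosomal protein genes were higher in 33 of 55 cases and lower in 2 (5.11e-12, and 0.168), against 27 and 6 after quantile normalization. Cathepsin genes, which encode lysosomal proteases, were higher in 4 of 10 cases and lower in 0 (0.00266, and 0.271). Zinc finger genes, with 6 of 338 higher and 30 lower (0.00396), vacuolar ATPase genes (7 of 17 higher, 0.00827), annexins (1 of 8 higher, 0.0272) and mitochondrial ribosomal protein genes (13 of 75 higher and 2 lower, 0.0272, and 0.0503 after cyclic loess) also passed. S100 genes (3 of 8 higher) passed only after S100PBP was taken out (0.0322, against 0.0779 with it), the 1 call of a family that this changed. Histone genes (camera adjusted p = 0.473), TRIM genes (0.244) and C-type lectin genes (0.722) did not pass.

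In the mouse arrays, 31 of 76 mitochondrial ribosomal protein genes were higher and 12 lower in heterozygous cells (camera adjusted p = 0.0371, and 0.599 with an estimated correlation), a call not kept after cyclic loess (adjusted p = 0.117) or quantile normalization (0.193). Cytosolic ribosomal protein genes, with a mean log2 level of 12.98, fell in 32 of 45 cases and rose in 4 (adjusted p = 1.77e-05, and 0.599 with an estimated correlation). This call was not kept after cyclic loess (camera adjusted p = 0.117), where 4 rose and 15 fell. Nor was it kept after quantile normalization (0.135), where 16 rose and 6 fell. Proteasome genes fell in 18 of 38 cases and rose in 5 (adjusted p = 0.0371, and 0.599 with an estimated correlation), a call not kept after cyclic loess (adjusted p = 0.582) or quantile normalization (0.363). Cathepsin genes, higher in CAL-1, fell in 7 of 12 cases and rose in 1 in heterozygous cells (adjusted p = 0.0371, and 0.599 with an estimated correlation). Their call was not kept after cyclic loess (camera adjusted p = 0.958) or quantile normalization (0.363), where 6 rose and 3 fell. S100 genes rose in 4 of 9 cases and fell in 1, with S100a4 and S100a9 among the risers (adjusted p = 0.0959). The families tested numbered 13 in the mouse and 14 in the human comparison, and p-values are adjusted over them.

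Genes lower in heterozygous pDCs were over-represented among genes higher in CAL-1: 282 were shared where independent calls give 195.4 (odds ratio 1.76, Fisher's exact test adjusted p = 4.91e-12). The hypothesis that both calls depend on the level of the gene was set before it was tested. Matched genes higher in CAL-1 had a median mouse log2 level of 10.1 against 8.62 for the others, and within 10 strata of mouse level the common odds ratio was 0.943 (95% interval 0.793 to 1.12). The overlap is therefore consistent with a shared dependence on level, and within strata it was not detected. Of the other overlaps, higher in heterozygous cells with lower in CAL-1 also passed (188 shared against 161.5, odds ratio 1.25, adjusted p = 0.0292) and was not tested within strata. Higher in both (adjusted p = 0.113) and lower in both (0.558) did not pass. For the first overlap, after cyclic loess of the mouse arrays, without strata, the odds ratio was 1.22 (1.04 to 1.44).

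AXL, a receptor tyrosine kinase that marks a transitional dendritic cell state, was at least 33.1-fold higher in CAL-1, and its mouse gene Axl was 2.07-fold higher in heterozygous pDCs (log2 fold change 1.05 ± 0.12 SE). A hypothesis is that other genes of that state move with it. Without AXL, 10 of 13 listed mouse genes rose and 0 fell (camera p = 5.13e-06, and p = 0.0403 with an estimated correlation), and 4 of 10 human genes rose and 1, CD2, fell (camera p = 0.0307, and p = 0.153 with an estimated correlation). By the prediction as first written this counted as a fit, but the label was changed to undecided after the result was seen, since 9 of the 13 mouse and 7 of the 10 human genes are also in the lists tested before. Of the genes outside those lists, Tmem176b (log2 fold change 0.80 ± 0.11 SE), Tmem176a (0.50 ± 0.12) and Cd81 (0.42 ± 0.11) rose in the mouse, Ppp1r14a did not pass (0.22 ± 0.25), CD81 (2.32 ± 0.32) and SIGLEC6 (1.79 ± 0.48) rose in CAL-1, and TMEM176B did not pass (0.11 ± 0.87).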
